A study of Mus musculus with 9 samples.

How the data were processed

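RNA was measured by sequencing in 3 libraries each of the mouse tumour line LLC1 and its single-cell subclones SCC1 and SCC2, labelled as untreated cells. The deposited values were FPKM, computed by the authors with cufflinks per the series' design text, after read trimming with Trimmomatic, removal of poly-N and low-quality reads and alignment with hisat2. The same text names HTSeq-count and the DESeq package for the authors' own tests, whose tables were not used here, with thresholds of p 0.05 and a fold of 2. Versions of these tools and the annotation are not given in the sources used here, and the builds named in the submitters' processing notes were GRCm38 and mm10. The labels' protocols and the design text differ on the library kit: one names a SMARTER kit for mRNA after RNeasy extraction, the other a TruSeq stranded mRNA kit after mirVana extraction, sequenced as 150 bp paired ends. Whether counting used the strand is not given in the sources used here, so overlapping and antisense genes are uncertain, as are genes with near-identical copies such as Cd24a, Ly6g, Ftl1 and ribosomal protein genes (named from general knowledge, with copies not examined here). FPKM does not correct for a change in total RNA per cell, so all changes are relative to the other genes of a library.

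The table held 15768 symbols, each above 0 in at least 1 library, of which 15665 matched a symbol of the GRCm38 RefSeq table. Symbols in the table are newer than that build, so chromosomes were taken by symbol and no coordinates are printed. Since low FPKM values were whole multiples of a step, whole fragments were worked back: for all 12270 genes above 0 in all 9 libraries the values came out whole within 0.001 fragments (largest distance 4.27e-05). On simulated FPKM values with known fragments, 2651 of 2652 genes above 0 in all libraries came back right, up to a factor common to the counts of a gene. The same limit holds for the real values, among them 910 genes above 0 in 1 library only. Fragments were therefore taken as the smallest whole numbers. Recovered fragments ran from 17094808 to 19398657 per library. Counting error and any floor in fragments cover counting only, since amplified copies are not independent molecules. Pairs of libraries of one line differed by a chi-square per gene of 1.20 to 1.72, above the 1 that counting alone gives, so no pair was treated as one library.

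Groups came from the sample titles. Genes with FPKM of at least 1 in at least 3 of the 9 libraries were tested (10519 genes) on log2(FPKM + 1) with a pseudocount of 1, with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust options), all 9 libraries in one fit and the lines as the only factor. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Positions, figures and simulations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The gene lists were written before any value was seen, and no published source is given for them. They numbered 44, with 1288 entries, of which 1130 matched a symbol of the table. The 35 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera takes its degrees of freedom from the libraries, not the genes, so a call can be lost without correlated members. The p of fry tests whether the members of a list move, on balance, one way and does not compare them with other genes. Genes are named by a fixed rule: the 8 largest changes in each direction among called genes whose libraries did not overlap and whose higher mean was at least 5 FPKM, without predicted or clone names, up to 4 members with the smallest adjusted p of each list described, and Mki67, Pcna, Cdk1, Ccnd1, Myc and Cdkn1a. The 47 genes lower in both subclones and the 8 changed in opposite directions were chosen after their values were seen. Xist, Ddx3y, Eif2s3y, Kdm5d and Uty were not analysed here. Some genes that the naming rule selects are not reported here.

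On data simulated from the real genes and depths, with a seeded set of genes changed by known folds, the fit for SCC1 against LLC1 (10368 genes) recovered 95.5% of genes changed 1.5-fold, and 100% of those changed 2-fold and 4-fold. For SCC2 against LLC1 (10368 genes) it recovered 95.5%, 98.5% and 100%, and for SCC2 against SCC1 (10363 genes) 98.5%, 98.5% and 100%. Of unchanged genes 0.157%, 0.118% and 0.0984% were called in these comparisons. Of the 35 lists, which were not changed as lists but may hold changed genes, 0 were called. Genes were drawn independently with a common dispersion, without correlation between genes or differences between cultures. These shares are therefore not rates of false calls in the real data. Of genes changed 2-fold, 7 of 66, 8 of 67 and 3 of 65 reached a fitted change of 2-fold, since the pseudocount pulls changes towards 0.

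The limma and camera tests, the gene lists, the naming rule and the following alternatives were chosen before the data were examined. The alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, median-of-ratios, quantile and total scaling, the replicate number as a block, limma without trend, array weights, an adjusted p of 0.01, the submitters' unadjusted thresholds, a fit with only the 6 libraries compared, and leaving out each library. Added after seeing the data were limma-voom on the recovered fragments and the removal of chromosome medians. Overlap of the subclones under noise alone was simulated 100 times with unchanged lines against shared LLC1 libraries, which gives no chance overlap for lines with real changes. Chromosome medians were compared with 1000 random gene sets of the same size, and again after regression on GC content of the longest annotated transcript, length and expression, with GC content known for 98.2% of tested genes. Location among chromosomes was tested with Fisher's exact test, two-sided, with exact binomial intervals at 95%.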

Results

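RNA-seq was used to compare LLC1, a cell line from a mouse Lewis lung carcinoma, with SCC1 and SCC2, subclones grown from single LLC1 cells by limiting dilution and kept in the same culture conditions for 5 to 8 passages. Each of the 3 lines had 3 libraries. The values were FPKM (fragments per gene, scaled by gene length and by the fragments of the library) for 15768 gene symbols, with totals of 381902 to 391805 per library and medians of 4.81 to 4.96. Whole fragments could be worked back from the FPKM values up to a factor common to the counts of a gene. Taken as the smallest whole numbers, they gave 17094808 to 19398657 fragments per library. At these depths 3 fragments on a gene of median length equalled 0.0430 to 0.0488 FPKM, so means near or below that level are not told apart from 0. The Spearman correlation across genes, which are not independent replicates, was 0.992 to 0.993 between libraries of one line and 0.977 to 0.984 between lines. Values below are mean FPKM ± SD over 3 libraries, log2 changes are on the log2(FPKM + 1) scale and understate the change of low genes, and adjusted p-values come from limma. No label says that the libraries of a line came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

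The comparison of SCC1 with LLC1 asked how the first subclone differed from its parent. SCC1 had lower transcript levels of collagens and matrix proteins than LLC1. Stc1, which encodes the secreted glycoprotein stanniocalcin 1, had 23.7 ± 0.799 FPKM in LLC1 and 0.57 ± 0.0613 in SCC1 (n = 3 each). Ptn, which encodes the heparin-binding growth factor pleiotrophin, went from 25.6 ± 0.82 to 1.26 ± 0.0756 FPKM. Of the 34 tested collagens and matrix proteins, 31 were lower and 3 higher, with a median log2 change of -0.72 (camera adjusted p = 2.09e-14), and -0.44 with no filter on low values. All 4 tested fibroblast markers were lower as well (median -0.55), of which Col3a1 and Dcn are also on the matrix list and Pdgfra on the mesenchymal list. Of 19 tested p53 targets, 14 were higher and 3 lower (adjusted p = 0.00418, and adjusted p = 0.129 with an estimated correlation).

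The other genes with the largest falls in SCC1 were Cthrc1, a secreted protein with a collagen-like repeat (log2 change -3.72, SE 0.0566, limma adjusted p = 1.19e-12), Anxa6, a calcium-dependent membrane-binding annexin (-3.01), Sema3f, a secreted semaphorin (-2.99), Dipk2a (-2.65), Dkk1, a secreted Wnt antagonist (-2.59), and Nradd (-2.51). Dkk1 had 5.3 ± 0.288 FPKM in LLC1 and 0.0471 ± 0.0222 in SCC1, the latter at the level of 3 fragments. The largest rises were in Marcks, a substrate of protein kinase C (log2 change 2.6, SE 0.0447, limma adjusted p = 2.35e-12), Acap1, which activates the GTPase of ARF proteins (2.09), and Rbp4, the plasma carrier of retinol (1.97). Cd300lb, a myeloid immunoreceptor, Pmaip1, which encodes the BH3-only protein NOXA, Snap25, a SNARE protein of exocytosis, Lif, a cytokine of the interleukin 6 family, and Padi2, a peptidylarginine deiminase, rose by log2 changes of 1.65, 1.64, 1.6, 1.58 and 1.55. Rbp4 went from 23.4 ± 0.587 to 94.9 ± 4.14 FPKM and Lif from 3.01 ± 0.246 to 11 ± 0.176 FPKM.

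The matrix genes that fell in SCC1 included Sparc, a collagen-binding matrix glycoprotein, from 183 ± 2.64 to 69.2 ± 0.816 FPKM, Fbn1, the microfibril protein fibrillin 1, from 18.9 ± 0.503 to 3.63 ± 0.0155, Col3a1, the fibrillar collagen III chain, from 575 ± 13.1 to 257 ± 5.0, and Col6a1 from 86.6 ± 0.333 to 30.5 ± 1.41. Of 24 tested mesenchymal genes, 18 were lower and 2 higher (median -0.30, camera adjusted p = 2.06e-05, and a median of -0.16 with no filter on low values). Fibronectin Fn1 had 449 ± 1.25 FPKM in LLC1 and 310.4 ± 0.979 in SCC1, and the hyaluronan receptor Cd44 86.2 ± 1.0 and 56.8 ± 0.665. Of 25 integrins and adhesion receptors, 16 were lower and 5 higher (adjusted p = 0.00234, but adjusted p = 0.0502 with an estimated correlation), among them Vcam1, a ligand of leukocyte integrins, at 38.4 ± 0.593 FPKM in LLC1 and 19 ± 0.332 in SCC1. Of 24 cholesterol synthesis genes, 19 fell and 2 rose (median -0.23, adjusted p = 1.38e-04). Of 19 genes of the unfolded protein response, 14 fell and 1 rose (median -0.16, adjusted p = 1.25e-04), including the endoplasmic reticulum chaperone Hsp90b1 (413 ± 12.7 to 297 ± 5.93 FPKM) and the disulfide isomerase Pdia6 (420.3 ± 6.94 to 312 ± 2.86).

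Among p53 targets in SCC1, Ccng1 rose from 87.3 ± 0.453 to 167 ± 0.451 FPKM, Trp53inp1 from 7.34 ± 0.0724 to 18 ± 0.692, Btg2 from 4.7 ± 0.243 to 11.7 ± 0.431, and Cdkn1a, the cyclin-dependent kinase inhibitor p21, from 115 ± 4.4 to 173 ± 4.23. Of 28 NRF2 targets, 17 rose and 6 fell (median 0.30, and 0.14 with no filter on low values, camera adjusted p = 0.0404, and adjusted p = 0.137 with an estimated correlation). The ferritin light chain Ftl1 rose from 2233 ± 34.1 to 3901 ± 49.8 FPKM, heme oxygenase Hmox1 from 24.6 ± 0.467 to 59.8 ± 1.14 and the quinone reductase Nqo1 from 14.5 ± 0.422 to 29.5 ± 0.63. The transketolase Tkt fell from 115 ± 1.19 to 76.4 ± 1.17 FPKM. Of 34 serine, one-carbon and ATF4 target genes, 21 fell and 9 rose (median -0.13, and -0.29 with chromosome medians removed, adjusted p = 0.00418, and adjusted p = 0.189 with an estimated correlation). They included the amino acid transporter Slc7a5 (103 ± 3.34 to 59.1 ± 0.902 FPKM) and the serine synthesis enzyme Psat1 (205 ± 1.79 to 147 ± 1.76). Of 21 fatty acid synthesis genes 11 fell and 3 rose (adjusted p = 0.0112, and adjusted p = 0.129 with an estimated correlation). Of 18 YAP/TAZ targets 11 fell and 3 rose (adjusted p = 0.0117, and adjusted p = 0.193 with an estimated correlation). Of 17 receptor tyrosine kinases 10 fell and 3 rose (adjusted p = 0.0112, and adjusted p = 0.172 with an estimated correlation). The call of NRF2 targets was also lost with quantile normalization (adjusted p = 0.0738) and in a fit of genes at 5 FPKM or more (0.0905). That of YAP/TAZ targets was also lost in the latter (0.0582). Over 21 alternatives the adjusted p ran from 3.30e-08 to 0.137 for NRF2 targets and from 1.22e-06 to 0.193 for YAP/TAZ targets. The lowest value of each came from fry, which does not compare a list with other genes.

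Markers of other cell types were measured beside these groups. Of 15 macrophage and leukocyte markers, 11 stayed under 1 FPKM in all 3 lines, and the 4 tested ones were all higher in SCC1. Of these 4, Mrc1 and Ly6g passed the filter of 1 FPKM only through SCC1, so their direction was set by the filter. Cd68 had 4.11 ± 0.351 FPKM in LLC1 and 9.14 ± 1.1 in SCC1, Cd14 12 ± 0.771 and 18.4 ± 0.932, Mrc1 0.267 ± 0.0504 and 2.11 ± 0.195, and Ly6g 0.0208 ± 0.0361 and 1.14 ± 0.0751. All 5 lymphocyte markers were under 1 FPKM in each line. Both tested endothelial markers were lower in SCC1 (median -0.16), and of 3 lung epithelial markers 2 were lower and 1 higher (median -0.21).

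The title of the series sets tumour growth against intrinsic proliferation, so cell cycle genes were examined on their own. In SCC1 30 of 50 cell cycle genes were higher and 9 lower, with a median log2 change of 0.11 (camera adjusted p = 0.0404, and adjusted p = 0.189 with an estimated correlation). Once chromosome medians were removed, the median of the cell cycle list was 0.0056 (adjusted p = 0.178, range 2.54e-06 with fry to 0.189 over 21 alternatives). The cell cycle call was also lost in a fit of genes at 5 FPKM or more (adjusted p = 0.0877), with limma without trend (0.0635), with quantile normalization (0.179), with median-of-ratios scaling (0.0539) and without LLC1 replicate 3 (0.0585). The proliferation antigen Mki67 had 67.5 ± 1.8 FPKM in LLC1 and 68.1 ± 0.717 in SCC1 (limma adjusted p = 0.672). The replication clamp Pcna was higher (201 ± 1.78 to 232 ± 3.43 FPKM), as were cyclin D1 Ccnd1 (175 ± 1.22 to 190.1 ± 2.56), Myc (184 ± 4.26 to 237 ± 1.87) and the ribonucleotide reductase subunit Rrm2 (92.7 ± 0.985 to 111 ± 1.34). The mitotic kinase Cdk1 was lower (37.2 ± 0.825 to 31.6 ± 0.793 FPKM), as were Cdc20 (88.4 ± 1.12 to 67.5 ± 0.863) and Ccnb2 (110.3 ± 2.31 to 78.4 ± 2.13). Once chromosome medians were removed, the fall of Cdk1 did not pass.

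In all, 7376 of 10519 tested genes (70.1%) passed an adjusted p of 0.05 in SCC1 against LLC1, 4127 higher and 3249 lower, and 201 of them changed by 2-fold or more, 52 higher and 149 lower. The share of lower genes among those was 74.1%, and 61.4% with quantile normalization. The 3 libraries of one line lay entirely above or below those of the other for 72.3% of genes, where chance gives 10%. Of 35 tested lists 12 passed camera, and 4 of these (collagens and matrix proteins, mesenchymal genes, cholesterol synthesis and the unfolded protein response) also did with an estimated correlation. That form of camera uses far fewer degrees of freedom, so a lost call there need not come from correlated members. Adjusted over the list alone, the counts of all lists were identical except for integrins and adhesion receptors (17 lower), ATF4 targets (22 lower), replication-dependent histones (4 higher against 3) and stem-cell and lineage factors (7 lower against 6). The number at 2-fold or more was 368 with a pseudocount of 0.1 and 401 with limma-voom on the recovered fragments.

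The comparison of SCC2 with LLC1 asked the same of the second subclone. SCC2 had almost no Grb10, an imprinted adaptor that restrains insulin receptor signalling, with 0.214 ± 0.0811 FPKM against 25 ± 0.456 in LLC1 (n = 3 each). Genes of the list of serine, one-carbon and ATF4 targets were higher: of 34 tested, 31 rose and 3 fell, with a median log2 change of 0.58 (camera adjusted p = 1.71e-11). Ribosomal protein genes were lower, 56 of 72 against 6 that rose, with a median of -0.13 (adjusted p = 6.82e-09, and adjusted p = 0.0639 with an estimated correlation). Cholesterol synthesis genes were lower as well, 21 of 24 against 2 (median -0.27, adjusted p = 7.35e-06).

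After Grb10 (log2 change -4.42, SE 0.0496, limma adjusted p = 9.44e-14), the largest falls in SCC2 were in the neighbouring genes of the membrane proteins Tmem176b (107 ± 2.35 to 9.12 ± 0.388 FPKM) and Tmem176a (65.9 ± 0.909 to 5.68 ± 0.458). Next were Glipr2 (log2 change -3.1), Dipk2a (-2.63), Sema3f (-2.54), Enpp2, the lysophospholipase D autotaxin (48.6 ± 0.962 to 7.58 ± 0.297 FPKM), and Disp2 (-2.5). The largest rises were in Dpt, the matrix protein dermatopontin (6.7 ± 0.216 to 29.8 ± 0.611 FPKM), Dkk1 (5.3 ± 0.288 to 21.4 ± 0.233), and Aldh1l2, a mitochondrial enzyme of folate metabolism (5.71 ± 0.0538 to 19.8 ± 0.27). Cdx2, a homeobox factor of the gut lineage, Atf5, a stress-response transcription factor, Gng11, a G protein gamma subunit, Gpnmb, a transmembrane glycoprotein, and Tmem74 rose by log2 changes of 1.48, 1.37, 1.36, 1.35 and 1.27. Dkk1 thus went below its LLC1 level in SCC1 and above it in SCC2.

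Among the ATF4 targets, Atf5 rose from 43.5 ± 1.12 to 114 ± 2.77 FPKM, Psat1 from 205 ± 1.79 to 359.9 ± 5.48 and Slc7a5 from 103 ± 3.34 to 196 ± 2.88. Of 19 unfolded protein response genes, 17 rose and 1 fell (median 0.19, camera adjusted p = 5.38e-04, and adjusted p = 0.0594 with an estimated correlation). Herpud1, of endoplasmic reticulum degradation, rose from 24.3 ± 0.603 to 38.9 ± 0.39 FPKM, and the chaperone Hspa5 from 372 ± 2.92 to 472 ± 1.47. The sterol genes that fell included Insig1 (41.1 ± 0.148 to 29.6 ± 0.411 FPKM), Mvd (33.1 ± 0.633 to 19.4 ± 0.589) and squalene epoxidase Sqle (101 ± 1.76 to 78 ± 1.36). Of 21 fatty acid synthesis genes 14 fell and 2 rose (adjusted p = 6.46e-04, and adjusted p = 0.0611 with an estimated correlation), among them the acetyl-CoA synthetase Acss2 (19.9 ± 0.279 to 10.2 ± 0.223 FPKM). The ribosomal protein genes with the smallest adjusted p were Rpsa (1422 ± 8.8 to 1056 ± 8.07 FPKM), Rpl17 (614 ± 8.74 to 443 ± 6.64) and Rps14 (1378 ± 29.1 to 927 ± 21).

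A further 9 lists passed camera as lower in SCC2, and 0 of these 9 passed with an estimated correlation. Of 18 YAP/TAZ targets 17 fell and 1 rose (median -0.28, camera adjusted p = 4.89e-05, and adjusted p = 0.0639 with an estimated correlation). The angiomotin-like gene Amotl2 had 12.5 ± 0.371 FPKM in LLC1 and 6.76 ± 0.211 in SCC2, and the receptor kinase Axl 136 ± 1.66 and 107 ± 1.43. Of 15 TGF-beta targets 11 fell and 1 rose (median -0.30, adjusted p = 7.68e-04, and adjusted p = 0.0594 with an estimated correlation), including Tgfb1 itself (14 ± 0.286 to 6.41 ± 0.334 FPKM) and Id3 (125 ± 2.2 to 66.2 ± 0.922). Of 28 NRF2 targets 17 fell and 5 rose (adjusted p = 0.00444, and adjusted p = 0.0639 with an estimated correlation), with Ftl1 going from 2233 ± 34.1 to 1394 ± 13.8 FPKM. Of 18 stem-cell and lineage factors 12 fell and 5 rose (adjusted p = 0.00444, and adjusted p = 0.0639 with an estimated correlation). The intermediate filament gene Nes fell from 18.5 ± 0.30 to 2.78 ± 0.0404 FPKM and Cd24a rose from 0.135 ± 0.0208 to 3.5 ± 0.398. Of 12 complement and coagulation genes 9 fell and 1 rose (adjusted p = 0.00865, and adjusted p = 0.0672 with an estimated correlation), with urokinase Plau falling from 89.4 ± 0.462 to 34.6 ± 0.64 FPKM. Of 9 epithelial genes 6 fell and 2 rose (adjusted p = 0.0119, and adjusted p = 0.0739 with an estimated correlation), including the keratins Krt8 (113 ± 1.14 to 75.3 ± 1.74 FPKM) and Krt18 (223 ± 3.6 to 157 ± 1.53). Of 6 imprinted genes 5 fell and 0 rose (adjusted p = 0.00413, and adjusted p = 0.0672 with an estimated correlation). Of 17 receptor tyrosine kinases 12 fell and 2 rose (adjusted p = 0.00444, and adjusted p = 0.0918 with an estimated correlation). Of 14 checkpoint and NK-cell ligands 9 fell and 2 rose (adjusted p = 0.0307, and adjusted p = 0.267 with an estimated correlation). The poliovirus receptor relative Nectin2 had 3.95 ± 0.297 FPKM in LLC1 and 0.656 ± 0.16 in SCC2. With no filter on low values the calls of the complement and coagulation (adjusted p = 0.114, range 2.96e-08 with fry to 0.114), epithelial genes (0.0922, range 3.72e-08 with fry to 0.0922) and checkpoint and NK-cell ligands (0.114) lists were lost. That of checkpoint and NK-cell ligands was also lost in a fit of genes at 5 FPKM or more (adjusted p = 0.226) and with limma-voom (0.0577, range 1.74e-05 with fry to 0.267).

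Among markers of other cell types, 2 of 3 tested lung epithelial markers were higher in SCC2 and 0 lower (median 0.26). Of 4 fibroblast markers 2 were higher and 2 lower (median -0.046), of 4 macrophage and leukocyte markers 1 was higher and 1 lower (median -0.033), and of 2 endothelial markers 0 were higher and 1 lower (median -0.16).

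In SCC2 25 of 50 cell cycle genes were higher and 11 lower, with a median log2 change of 0.083 (camera adjusted p = 0.030, and adjusted p = 0.142 with an estimated correlation). The cell cycle call was also lost in a fit of genes at 5 FPKM or more (adjusted p = 0.0742) and with quantile normalization (0.228, range 2.68e-06 with fry to 0.228 over 21 alternatives). Mki67 was higher (67.5 ± 1.8 to 76.5 ± 2.22 FPKM), as were Cdk1 (37.2 ± 0.825 to 42.8 ± 0.917), Ccnb1 (68.8 ± 0.602 to 94.4 ± 1.11), Ccne2 (7.11 ± 0.115 to 13 ± 0.402), Pcna (201 ± 1.78 to 219 ± 3.72) and Myc (184 ± 4.26 to 229.9 ± 5.19). Cdkn1a was lower (115 ± 4.4 to 105 ± 0.817 FPKM, limma adjusted p = 0.00146), with a log2 change of 0.0013 once chromosome medians were removed. Ccnd1 had 175 ± 1.22 FPKM in LLC1 and 187 ± 1.22 in SCC2, a rise (limma adjusted p = 3.41e-04) that did not pass with quantile normalization (adjusted p = 0.139).

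Of 10519 tested genes 7112 (67.6%) passed in SCC2 against LLC1, 3655 higher and 3457 lower, and 166 changed by 2-fold or more, 25 higher and 141 lower. The share of lower genes among those was 84.9%, and 71.2% with quantile normalization. The libraries of the 2 lines did not overlap for 70.7% of genes, where chance gives 10%. Camera called 15 of 35 lists, of which the ATF4 targets and cholesterol synthesis also passed with an estimated correlation (adjusted p = 0.0482 and 0.0482). Adjusted over the list alone, the counts of all lists were identical except for fatty acid synthesis (15 lower, 3 higher), ribosomal proteins (7 higher) and stem-cell and lineage factors (13 lower). They differed also for integrins and adhesion receptors (14 lower against 13), glycolysis and hypoxia targets (16 higher against 15) and DNA sensing and innate receptors (3 higher against 4). The number at 2-fold or more was 357 with a pseudocount of 0.1 and 388 with limma-voom.

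The changes of both subclones were set against each other, since each was compared with the same LLC1 libraries. Genes lower by 2-fold or more in both subclones numbered 47, where independent lists would share 2.00, and they included Cthrc1, Anxa6, Enpp2, Nes, Sema3f, Glipr2 and Dipk2a. The count was 16 in a fit of genes at 5 FPKM or more, 84 with a pseudocount of 0.1, 88 with limma-voom and 97 with libraries scaled to the same FPKM total. The median of the 47 was 2.996 FPKM in LLC1, 0.0994 in SCC1 and 0.102 in SCC2. A single gene, Cd300lb, was higher by 2-fold or more in both, where independent lists would share 0.124. That count was 0 without SCC2 replicate 3, 3 with a pseudocount of 0.5, 3 with quantile normalization, 4 with the same FPKM total, 8 with a pseudocount of 0.1 and 10 with limma-voom. The 8 genes changed by 2-fold or more in opposite directions, named here after their values were seen, were Dkk1 and Col6a2, lower in SCC1 and higher in SCC2, and Rbp4, Crmp1, Ly9, Renbp, Selenop and Bhlhb9, higher in SCC1 and lower in SCC2. Over all genes called, 1539 were higher in both subclones, where independent lists would share 1434, 1334 were lower in both (1068), and 2357 went opposite ways (2485). The correlation of the log2 changes across genes was 0.162. Simulated unchanged lines against shared controls gave 0.503, which follows from the shared controls when nothing changes and is no reference for lines with real changes. The covariance of the log2 changes was 0.0188, against 0.00122 from that simulated noise. Simulations of unchanged lines called 0 genes in both, which gives no chance overlap for lines with real changes. Part of the excess over independent lists may come from the shared LLC1 libraries, which are too few to split.

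**Figure D1:**
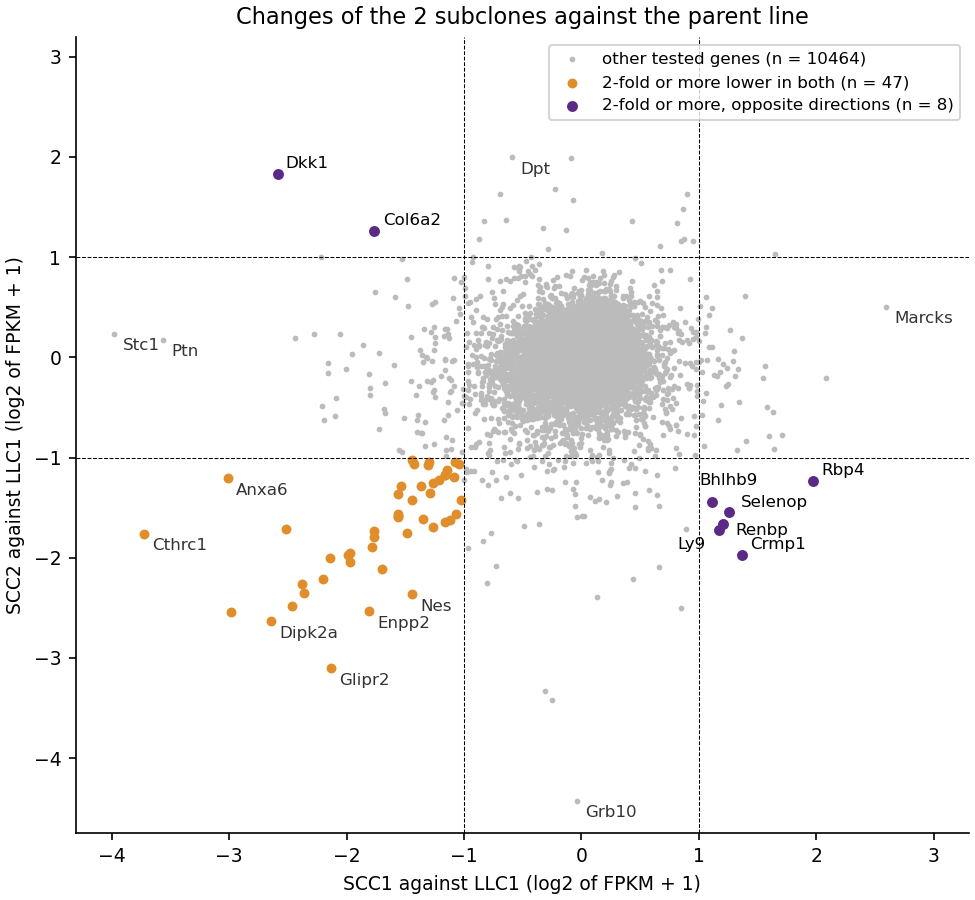
Log2 change of each tested gene on the log2(FPKM + 1) scale in SCC1 against LLC1 (x axis) and in SCC2 against LLC1 (y axis), with dashed lines at a 2-fold change. Orange points are the 47 genes lower by 2-fold or more in both subclones, purple points the 8 changed by 2-fold or more in opposite directions, and grey points the other tested genes.

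The comparison of SCC2 with SCC1 asked how the subclones differed from each other. By camera at the preset correlation, the lists of matrix proteins, ATF4 targets and the unfolded protein response were higher in SCC2 than in SCC1 and those of p53 and NRF2 targets lower, and none of them passed with an estimated correlation (adjusted p = 0.0602 to 0.0973). Dkk1 had 21.4 ± 0.233 FPKM in SCC2 and 0.0471 ± 0.0222 in SCC1, and Stc1 had 28.1 ± 0.445 and 0.57 ± 0.0613 (n = 3 each). Of 34 collagens and matrix proteins, 25 were higher in SCC2 and 7 lower, with a median log2 difference of 0.66 (camera adjusted p = 1.57e-05, and adjusted p = 0.0865 with an estimated correlation), and a median of 0.17 with no filter on low values. Of 4 tested fibroblast markers 2, Col3a1 and Dpt, were higher by 2-fold or more and 1, Pdgfra, was lower (median 0.67). Of 3 lung epithelial markers 2 were higher, 1 of them by 2-fold or more, and 1 lower (median 0.47), and of 2 endothelial markers 1 was higher and 1 lower. Of 34 serine, one-carbon and ATF4 target genes, 29 were higher and 4 lower, with a median of 0.55 (adjusted p = 1.37e-08, and adjusted p = 0.0643 with an estimated correlation).

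The genes highest in SCC2 relative to SCC1 were Dkk1 (log2 difference 4.42, SE 0.0425, limma adjusted p = 1.12e-14), Stc1 (4.21), Ptn (3.74), the linker histone gene H1f10 (3.21), Col6a2 (3.02), Dpt (2.59), Thbs1, the matricellular protein thrombospondin 1 (2.51), and Plac9a (2.5), whose reads may be shared with a near-identical copy. The genes lowest in SCC2 were Grb10 (-4.39), Disp2 (-3.35), Crmp1, a cytosolic phosphoprotein of neurons (-3.34), Rbp4 (-3.21), Tmem176b (-3.17), Tmem176a (-3.02), Ly9, a receptor of the SLAM family (-2.89), and Renbp, a renin-binding epimerase (-2.88). Col6a1 had 124 ± 0.864 FPKM in SCC2 and 30.5 ± 1.41 in SCC1, Col3a1 699 ± 12 and 257 ± 5.0, and Thbs1 25.8 ± 0.884 and 3.71 ± 0.166.

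Of the ATF4 targets, Atf5 had 114 ± 2.77 FPKM in SCC2 and 27.6 ± 0.122 in SCC1, Slc7a5 196 ± 2.88 and 59.1 ± 0.902, and the mitochondrial serine enzyme Shmt2 256 ± 5.31 and 101 ± 2.2. Of 19 unfolded protein response genes 16 were higher in SCC2 and 1 lower (median 0.43, camera adjusted p = 1.57e-05, and adjusted p = 0.0602 with an estimated correlation). They included Herpud1 (38.9 ± 0.39 against 18.7 ± 0.0635 FPKM) and Hsp90b1 (489.8 ± 4.85 against 297 ± 5.93). Of 19 p53 targets 15 were lower in SCC2 and 2 higher (median -0.42, adjusted p = 0.00105, and adjusted p = 0.0973 with an estimated correlation). Ccng1 had 72.1 ± 1.08 FPKM in SCC2 and 167 ± 0.451 in SCC1, Pmaip1 0.73 ± 0.0667 and 9.19 ± 0.225, and Cdkn1a 105 ± 0.817 and 173 ± 4.23. Of 28 NRF2 targets 22 were lower in SCC2 and 4 higher (median -0.36, adjusted p = 2.94e-04, and adjusted p = 0.0602 with an estimated correlation), with Ftl1 at 1394 ± 13.8 against 3901 ± 49.8 FPKM and Hmox1 at 20.2 ± 0.874 against 59.8 ± 1.14. Of 72 genes of the list of ribosomal proteins 42 were lower and 17 higher (median -0.089, adjusted p = 0.048, and adjusted p = 0.679 with an estimated correlation). The call of ribosomal proteins was lost in 10 of 21 alternatives (adjusted p from 5.22e-06 with fry to 0.679). Besides the estimated correlation, it was lost without SCC1 replicate 1 (adjusted p = 0.0514), without SCC1 replicate 3 (0.0524), without SCC2 replicate 1 (0.0686) and in a fit of genes at 5 FPKM or more (0.057). It was also lost with the replicate number as a block (adjusted p = 0.0579), with median-of-ratios scaling (0.0698), with the same FPKM total (0.0852), without trend (0.106) and with quantile normalization (0.405, median -0.049).

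Chemokine and cytokine lists were compared between the subclones. Of 8 tested chemokines 5 were lower in SCC2 and 1 higher, and the list did not pass (camera adjusted p = 0.291). The monocyte chemokines Ccl2 and Ccl7 had 94.7 ± 5.83 and 5.05 ± 0.526 FPKM in SCC2 and 144 ± 3.34 and 9.41 ± 0.0489 in SCC1. Of 11 cytokines and colony-stimulating factors 5 were higher and 4 lower, with a median log2 difference of 0.12 and a mean of -0.20 (adjusted p = 0.896). Lif had 1.84 ± 0.197 FPKM in SCC2 and 11 ± 0.176 in SCC1, osteopontin Spp1 484 ± 10.9 and 697 ± 10.3, and the Kit ligand Kitl 32.5 ± 0.606 and 19.3 ± 1.03. The 4 tested macrophage and leukocyte markers were all lower in SCC2 than in SCC1, with Cd68 at 3.05 ± 0.236 and 9.14 ± 1.1 FPKM. Mrc1 and Ly6g were tested only because of their level in SCC1, which set their direction. For Cd14 the log2 difference of -0.22 turned to 0.24 once chromosome medians were removed.

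Of 50 cell cycle genes 19 were higher in SCC2 and 25 lower, with a median of -0.032 (camera adjusted p = 0.933). That median was 0.049 with chromosome medians removed (adjusted p = 0.444, range 0.444 to 0.971 over 21 alternatives) and -0.0036 with libraries scaled to the same FPKM total. Mki67 was higher in SCC2 (76.5 ± 2.22 against 68.1 ± 0.717 FPKM), as was Cdk1 (42.8 ± 0.917 against 31.6 ± 0.793), while Kif20a (41.5 ± 0.738 against 60.8 ± 0.868) and Ccnf (38.6 ± 1.14 against 56.2 ± 1.21) were lower. Pcna had 219 ± 3.72 FPKM in SCC2 and 232 ± 3.43 in SCC1, a fall of limma adjusted p = 0.00134 that turned to a log2 difference of 0.064 once chromosome medians were removed. Myc had 229.9 ± 5.19 and 237 ± 1.87 FPKM (adjusted p = 0.0827), a fall that passed without SCC2 replicate 3 (adjusted p = 0.022), with quantile normalization and with limma-voom, and a log2 difference of 0.38 once chromosome medians were removed. Ccnd1 had 187 ± 1.22 and 190.1 ± 2.56 FPKM (adjusted p = 0.181).

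Of 10519 genes 8031 (76.3%) passed between the subclones, 3890 higher and 4141 lower in SCC2, and 352 differed by 2-fold or more, 158 higher and 194 lower. The libraries did not overlap for 77.9% of genes, where chance gives 10%. For 300 of the 352 genes (85.2%) the LLC1 mean lay between those of the subclones, for 48 it lay above both and for 4 below both. Choosing genes for a large difference between the subclones by itself favours a parent mean between them, and no chance share was computed. Camera called 6 of 35 lists and 0 with an estimated correlation, where 9 and 7 lists had an unadjusted p under 0.05, and fry called 33. Adjusted over the list alone, the counts of all lists were identical except for NF-kB targets (11 lower against 10) and immediate early genes (12 higher against 11). The number at 2-fold or more was 607 with a pseudocount of 0.1 and 662 with limma-voom.

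**Figure D2:**
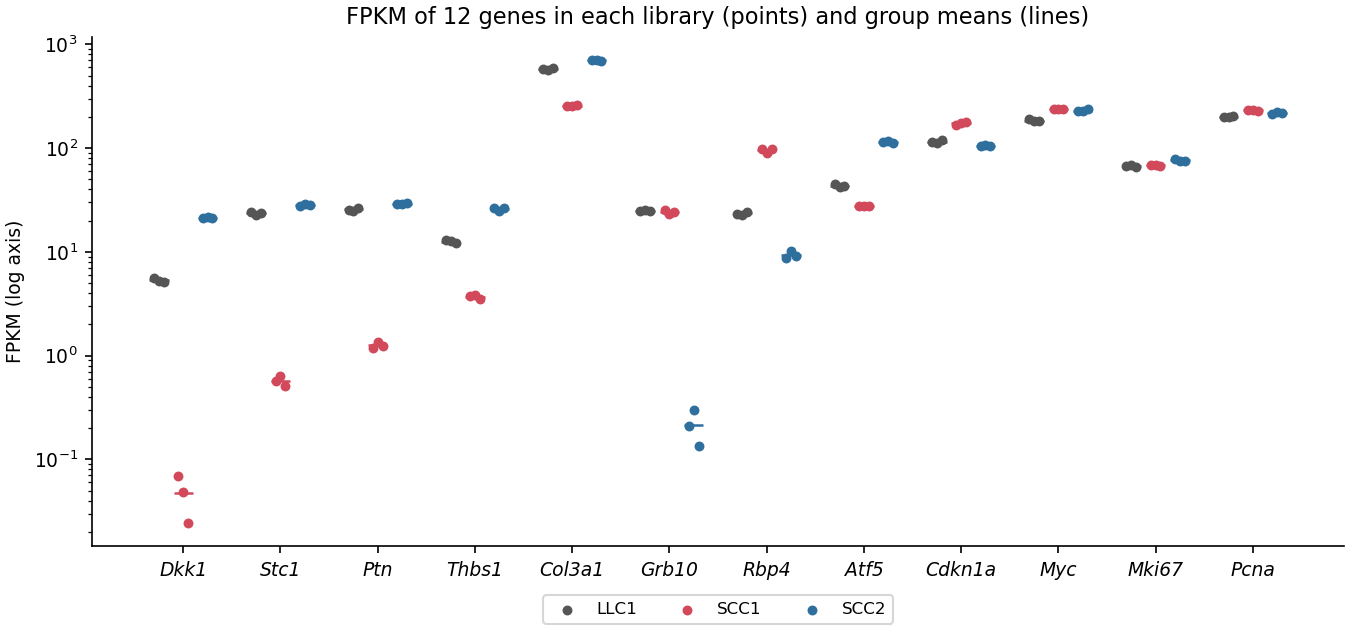
FPKM on a log axis of 12 genes in each of the 9 libraries (points, coloured by line) with the mean of each line as a horizontal bar. Dkk1, Stc1 and Ptn are lowest in SCC1 and Grb10 is lowest in SCC2, while Mki67 and Pcna differ little between the lines on this scale.

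**Figure D3:**
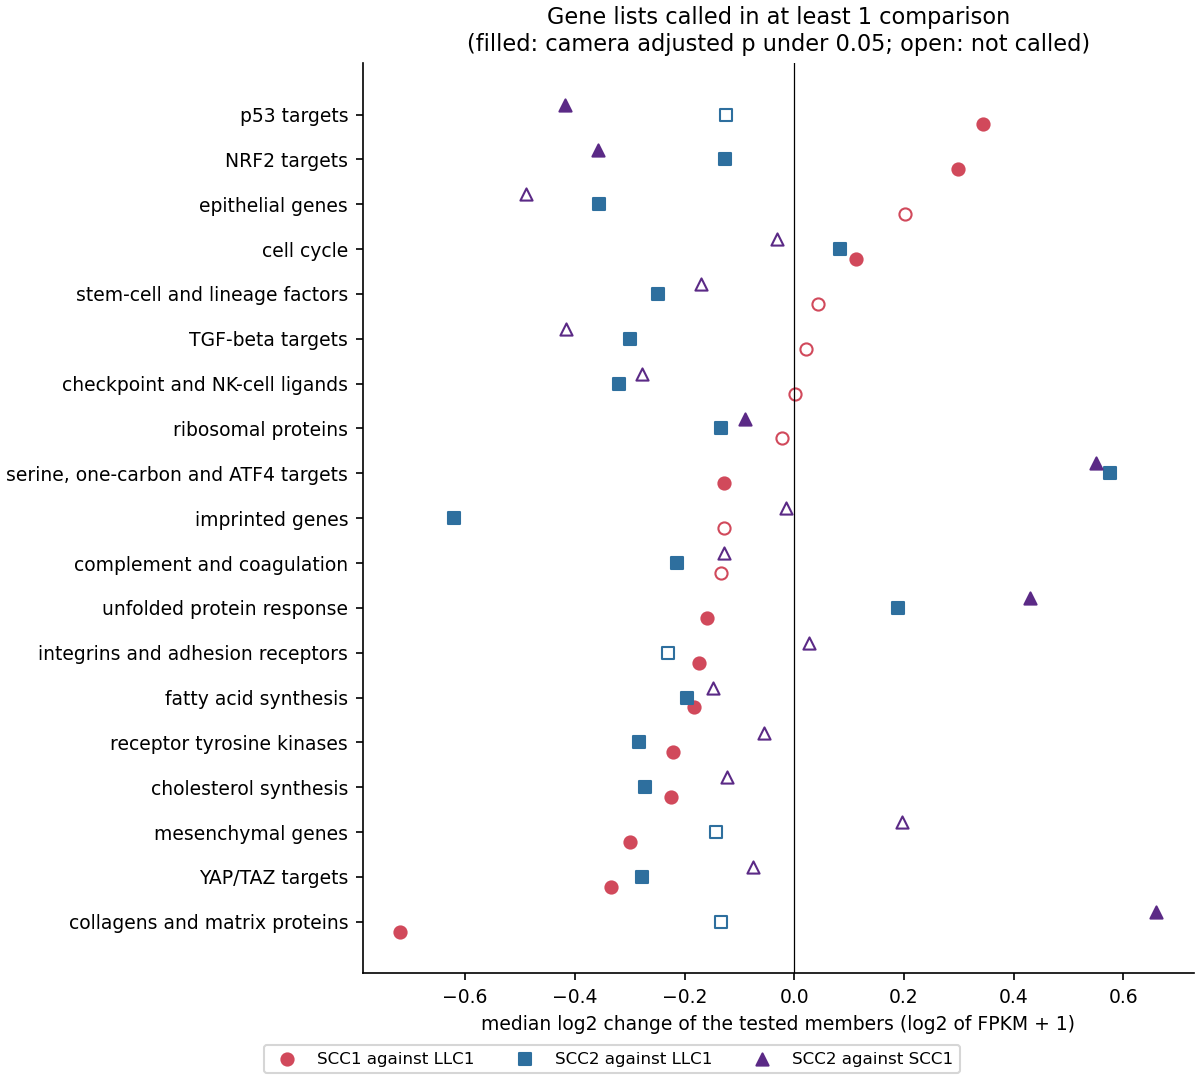
Median log2 change of the tested members of each gene list that passed camera in at least 1 comparison, with a symbol for each comparison, filled where the list passed and open where it did not. The ATF4 target list lies at -0.13 in SCC1 and 0.58 in SCC2 against LLC1, and the collagen list at -0.72 in SCC1.

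Genes were also grouped by chromosome, using the 10501 tested genes with a position in the GRCm38 RefSeq annotation. In each comparison the genes of several chromosomes shifted together. In SCC1 against LLC1 the genes of chromosome 4 had a median log2 change of -0.33, with 92.8% of 614 genes on the lower side of the genome-wide median, and those of chromosome 18 had a median of 0.22 (84.5% of 265 genes on the higher side). In SCC2 against LLC1 the medians were 0.35 for chromosome 13 (87.2% of 405 genes) and -0.26 for chromosome 15 (90.5% of 431 genes). On chromosome 12 the genes nearer the start and nearer the end differed in sign, with medians of -0.082 and 0.18 in SCC1 against LLC1, 0.14 and -0.076 in SCC2 against LLC1, and 0.20 and -0.25 in SCC2 against SCC1. Between SCC2 and SCC1 the widest medians were -0.46 for chromosome 18, -0.44 for chromosome 15 and 0.29 for chromosome 4. Chromosomes with a median beyond all of 1000 random gene sets of the same size and at least 65% of genes on one side numbered 10 of 20 in SCC1 against LLC1, 12 in SCC2 against LLC1 and 11 in SCC2 against SCC1. With the median of each chromosome removed from each library, 6391, 6194 and 7049 genes passed in the 3 comparisons, in that order.

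**Figure D4:**
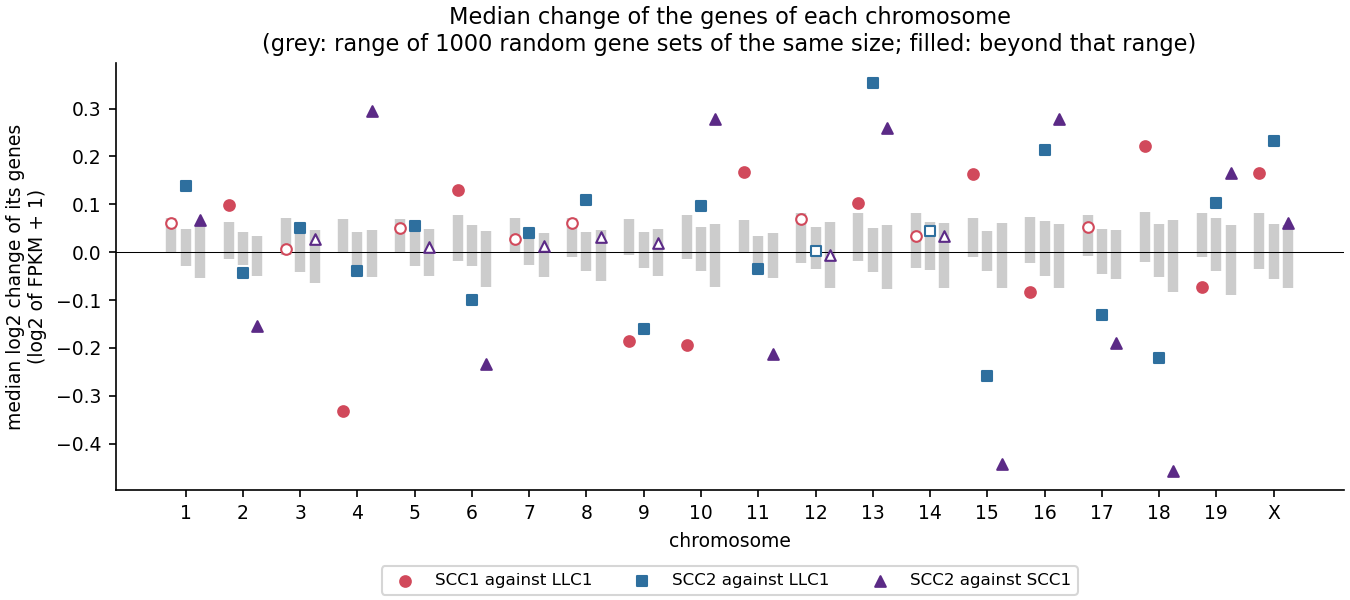
Median log2 change of the genes of each chromosome (y axis) by chromosome (x axis), with a symbol for each comparison, filled where it lies beyond the range of 1000 random gene sets of the same size, drawn as grey bars. Chromosome 4 lies at -0.33 in SCC1 against LLC1, and chromosome 13 at 0.35 in SCC2 against LLC1.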

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

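In this part, the tests of GC content and length, of the shared LLC1 libraries, of chromosome 9 and of chromosome shifts behind the ATF4 and unfolded protein response lists were chosen after the result was seen, and those of chromosome copy number and of other splits before. The results listed were picked because the change against LLC1 differed between the subclones, as tested by SCC2 against SCC1 itself. By camera, the median log2 difference (SCC2 minus SCC1) was 0.66 for collagens and matrix proteins, 0.55 for serine, one-carbon and ATF4 targets, 0.43 for the unfolded protein response, -0.42 for p53 targets, -0.36 for NRF2 targets and -0.089 for ribosomal proteins, and none passed with an estimated correlation (adjusted p = 0.0602 to 0.679). By limma, the log2 difference was 4.42 for Dkk1, 3.02 for Col6a2, -3.34 for Crmp1, -3.21 for Rbp4, -2.89 for Ly9, -2.88 for Renbp, -2.79 for Selenop and -2.56 for Bhlhb9, each changed by 2-fold or more in opposite directions against LLC1.

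The 3 libraries of each line against 3 of another make 10 splits, too few for a share under 0.05, so 1 of 10 splits was the smallest that could be reached in each comparison. The real splits called 7376, 7112 and 8031 genes for SCC1 against LLC1, SCC2 against LLC1 and SCC2 against SCC1, and the highest of the other splits called 0 by limma, with 153, 151 and 79 genes at an unadjusted p under 0.05.

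The first pattern is the shift of genes of one chromosome in one direction. A difference in chromosome copy number predicts chromosomes with a median beyond all 1000 random sets and at least 65% of genes on one side, and these numbered 10 in SCC1 against LLC1, 12 in SCC2 against LLC1 and 11 in SCC2 against SCC1. Chromosome 12, picked after its values were seen, was not among them, and its genes nearer the start and nearer the end had medians of opposite sign in each comparison (0.20 and -0.25 in SCC2 against SCC1). After regression on GC content, length and expression level the numbers were 10, 12 and 11 again, which argues against those as the whole cause. A difference in copy number between the lines remains a candidate explanation and a hypothesis, since no DNA was measured, and chromosome-wide regulation of expression was not tested.

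The second pattern is the set of 47 genes lower by 2-fold or more in both subclones, a count that ran from 16 (genes at 5 FPKM or more) to 97 (same FPKM total) over the alternatives. In each of the 47 genes the range of the 3 LLC1 libraries was at most 0.309 of the smaller fall (median 0.0716). The genes were chosen for large falls against these same libraries, so a small range follows from the choice and cannot decide their role. Without 1 LLC1 library 44 to 50 genes were lower in both, so no single LLC1 library carried the set. A shift common to the 3 LLC1 libraries could not be tested. Growth from a single cell and the passages after it were common to both subclones, so any effect of these could not be told apart. Of the 47 genes, 22 lie on chromosome 9 (46.8%, exact 95% interval 32.1 to 61.9), against 5.56% of all tested genes (odds ratio 15.5, Fisher's exact p = 6.75e-16). For those 22 this argues against cells of another type in the LLC1 culture, if the genes of such cells lie across the chromosomes. The interval and the test treat genes as independent, though genes of one chromosome shifted together, and chromosome 9 was picked after its genes were seen. Of the 101 genes with a known position lower by 2-fold or more in SCC1 alone 7 lie there, and of the 94 in SCC2 alone 1. LLC1 cells with transcribed chromosome 9 genes that both subclones lack may account for the 22, as a hypothesis found and tested on the same data, while the other 25 genes stay open.

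The third pattern is the opposite direction of the ATF4 target and unfolded protein response lists in the subclones, by camera at the preset correlation. With an estimated correlation the lower ATF4 targets of SCC1 did not pass (camera adjusted p = 0.189), nor did the higher unfolded protein response of SCC2 (0.0594). The differences between the subclones did not pass either (0.0643 and 0.0602), so the pattern itself is uncertain. That form of camera uses far fewer degrees of freedom, so these lost calls alone do not show that correlated members made the pattern. The estimate was 0.0583 for the ATF4 targets but -0.0124 for the unfolded protein response, below the preset 0.01. A higher correlation of its members therefore did not undo the calls of the unfolded protein response, and the fewer degrees of freedom did. The unadjusted camera p of that list in SCC2 against SCC1 went from 1.32e-06 to 0.00191. Chromosome-wide shifts could move a list whose members share chromosomes. With chromosome medians removed the median difference of SCC2 minus SCC1 was 0.77 for the ATF4 targets (0.55 before, adjusted p = 5.90e-10 at the preset correlation) and 0.45 for the unfolded protein response (0.43 before, adjusted p = 1.95e-07), which argues against such shifts as the whole cause. The state of the cultures at harvest, such as nutrients or density, could not be tested and stays open beside a heritable difference between the subclones.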

How the results depend on the processing

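All 3 comparisons kept their counts of called genes within 1.5 times under each alternative run, and leaving out 1 library gave 6883 to 6988 genes for SCC1 against LLC1, 6680 to 6787 for SCC2 against LLC1 and 7670 to 7710 for SCC2 against SCC1. Limma-voom and the removal of chromosome medians were chosen after seeing the data. Counts at 2-fold or more depended on the pseudocount, filter and scale: 201, 166 and 352 became 368, 357 and 607 with a pseudocount of 0.1, 110, 86 and 217 with FPKM of at least 5 in 3 libraries (fewer genes tested), 367, 343 and 612 with libraries scaled to the same FPKM total (11373 genes tested, so more than the scale differs), and 401, 388 and 662 with limma-voom on recovered fragments. With a pseudocount of 0.5 SCC2 against LLC1 had 258. Without 1 library they were 197 to 207, 161 to 171 and 349 to 360. The 47 genes lower in both became 84 (pseudocount 0.1), 16 (FPKM of at least 5), 97 (same FPKM total) and 88 (limma-voom), and 44 to 50 without 1 library. Lists called were 12, 15 and 6, and 4, 2 and 0 with camera at an estimated correlation, and 32, 33 and 33 with fry, which asks another question. Without 1 library they were 11 to 12, 15 and 5 to 8, and genes called the same way in both were 2604 to 2741. The estimated correlation lay below the preset 0.01 for some lists that lost their call, such as integrins and adhesion receptors (2.34e-05), NRF2 targets (1.20e-04) and epithelial genes (-0.0331). It lay above 0.01 for others, such as ribosomal proteins (0.0730) and YAP/TAZ targets (0.0677). In the former a higher correlation was not what undid the call, and the fewer degrees of freedom of that form of camera were. In the latter the correlation and the degrees of freedom changed together, and their parts were not separated.

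The cell cycle list of SCC1 against LLC1 kept its sign and lost its call with an estimated correlation (median 0.11, adjusted p = 0.189), FPKM of at least 5 (0.11, 0.0877), median-of-ratios scaling (0.096, 0.0539), quantile normalization (0.084, 0.179), limma without trend (0.11, 0.0635), chromosome medians removed (0.0056, 0.178) and without LLC1 replicate 3 (0.12, 0.0585). Its adjusted p ran from 2.54e-06 with fry to 0.189 over 21 alternatives, and its median from 0.11 to 0.12 without 1 library. In SCC2 against LLC1 the list lost its call with an estimated correlation (0.083, 0.142), FPKM of at least 5 (0.083, 0.0742) and quantile normalization (0.060, 0.228). There its adjusted p ran from 2.68e-06 with fry to 0.228, and its median from 0.067 to 0.101 without 1 library. Between the subclones, where the list did not pass, its median was 0.049 with chromosome medians removed (adjusted p = 0.444), -0.0036 with the same FPKM total, and -0.0386 to -0.0236 without 1 library. The estimated correlation of the cell cycle list was 0.0142, near the preset 0.01, while the degrees of freedom of that form of camera were far fewer. The causes of the other changes were not tested, apart from the smaller set of genes under the filter.

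Of 9046 values of named genes under alternatives, 9003 kept direction and side of the threshold. The 10 that reversed were, with quantile normalization, Mrc1 in SCC2 against LLC1 (0.34), and with chromosome medians removed, whose construction moves genes by chromosome, Gnas in SCC1 against LLC1 (-0.0053), Cdkn1a (0.0013), H1f2 (-0.044), Ly6g (0.23) and Abca3 (0.084) in SCC2 against LLC1, and Pcna (0.064), Myc (0.38), Atp5a1 (0.0026) and Cd14 (0.24) in SCC2 against SCC1. The cause for Mrc1 was not tested. Of 2199 values of lists under alternatives, 2056 stayed on the same side of the threshold, 52 lost the call, 87 gained it and 4 reversed. The 4 reversals were all with fry: angiogenesis factors in SCC2 against LLC1, and in SCC2 against SCC1 cytokines and colony-stimulating factors, receptor ligands and growth factors, and DNA sensing and innate receptors. The fit with the replicate number as a block called 7306, 7046 and 7962 genes, with 201, 166 and 352 at 2-fold or more, and among lists lost only the ribosomal proteins of SCC2 against SCC1 (adjusted p = 0.0579). Residuals of libraries with the same number correlated at -0.068 to 0.089, and 2 of 9 libraries correlated best with their own number, so the number was not taken to pair them. Depth limits what can be said of genes near 0.0430 to 0.0488 FPKM.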

Other observations

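In the first paragraph of this part the comparisons and lists were set before the values were seen, while which of the lists to describe was chosen after. All of the second paragraph was chosen after the values were seen: the genes lower in both subclones, their levels, the fall of 10-fold, the other genes of chromosome 9 and the tests of location. Of 37 glycolysis and hypoxia targets, 19 were higher in SCC2 than in SCC1 and 14 lower, and the list did not pass (camera adjusted p = 0.756). Slc16a3, a lactate transporter, had 19.3 ± 0.445 FPKM in SCC2, 4.09 ± 0.308 in SCC1 and 21.7 ± 1.04 in LLC1, and the glycolytic enzyme Eno1 had 2123 ± 10.1 FPKM in SCC2, 1328 ± 7.12 in SCC1 and 1843 ± 3.65 in LLC1. Of 21 angiogenesis factors 12 were higher in SCC2 and 7 lower (adjusted p = 0.197). Pgf, a growth factor of the VEGF family, had 0.667 ± 0.0787 FPKM in SCC2, 6.41 ± 0.247 in SCC1 and 3.67 ± 0.243 in LLC1, and the semaphorin and VEGF co-receptor Nrp2 had 42.5 ± 0.231 FPKM in SCC2, 13.8 ± 0.359 in SCC1 and 34.3 ± 0.749 in LLC1. Of 18 Wnt pathway genes 8 were higher and 7 lower (adjusted p = 0.945), and the ligand Wnt7b had 7.52 ± 0.348 FPKM in SCC2, 28.5 ± 0.677 in SCC1 and 15.6 ± 0.411 in LLC1. Of 18 genes of MHC class I antigen presentation 5 were higher in SCC2 and 10 lower (adjusted p = 0.748), with beta-2 microglobulin B2m at 232 ± 2.89 FPKM in SCC2, 308 ± 8.42 in SCC1 and 279 ± 5.85 in LLC1. Adjusted over the list alone these counts were identical. Each of the 6 genes named here passed limma between the subclones (adjusted p at most 1.26e-08, that of B2m).

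The 22 genes of chromosome 9 that were lower by 2-fold or more in both subclones included the adhesion molecules Ncam1, Cadm1 and Jam3, the methyltransferase Nnmt, the retinoic acid binding protein Crabp1 and the collagen chain Col5a3, all named after their values were seen. Their median was 2.52 FPKM in LLC1, 0.0361 in SCC1 and 0.0271 in SCC2, both under the level of 3 fragments at the median length. The other 562 tested genes of chromosome 9 had a median log2 change of -0.18 in SCC1 and -0.15 in SCC2 against LLC1. Of the 47 genes lower in both, 25 had a mean FPKM at least 10-fold lower in both, and 17 of these lie on chromosome 9. Chromosome 4 held 6 of the 47 (Fisher's exact p = 0.0546).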
